A study of Mus musculus with 9 samples.

How the data were processed

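RNA was taken from 4T1 mouse mammary carcinoma cells at day 2, in 9 libraries of 3 groups with 3 replicates each (NC, MK1775 and Wee1 siRNA). Per the labels' protocols, RNA was extracted with an RNeasy Mini Plus kit, and libraries were made from 1.0 µg of total RNA with an NEBNext Ultra kit. Whether poly(A) RNA was selected, whether strand was kept, the MK1775 dose and the siRNA sequences are not given in the sources used here, and neither is whether the numbers of the siRNA libraries stand for replicates or for different siRNAs. FastQC, Trim Galore, HISAT2 and StringTie are named, without versions, in the submitters' processing notes, with the genome build GRCm39. The authors deposited FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library), 1 value per transcript and library, for 158719 transcripts. Per the file headers and names, these are reference transcripts together with 17991 assembled transcripts that carry no gene name. No counts were used, and low FPKM values were checked for whole multiples of a common step: the share within 0.1 of a whole multiple was 19.4% to 21.9% per library, about what evenly spread values give, so the reads could not be recovered and the depth is unknown. Each column was assigned to its library through the column name quoted in the sample's description.

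For the main values, FPKM of all transcripts with the same gene name were summed, giving 52306 genes; 19 names found on more than 1 chromosome were left out, as were transcripts without a gene name. Genes with a mean of at least 1 FPKM over the 9 libraries were tested (10453), on log2(FPKM + 1). Fold changes on this scale understate the change of low genes. Coordinates are those of the deposited table (GRCm39), as the span of a gene's named transcripts; the reference genome at hand was of another build and was not used here. Strand-aware counting is not stated, so reads of overlapping or antisense genes cannot be told apart.

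Tests were made in R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table, and figures with matplotlib 3.10.9. All 9 libraries entered a single limma fit with 3 group means and no covariate (lmFit, contrasts.fit, eBayes with trend), with 3 contrasts: MK1775 minus NC, Wee1 siRNA minus NC, and MK1775 minus Wee1 siRNA. Tests were two-sided with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Values given as mean ± SD are FPKM over 3 libraries. An exact permutation test of 3 against 3 cannot give a p below 0.1.

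Gene lists, 27 with 819 entries in all, were written from textbook knowledge: suppressors of ferroptosis, promoters and markers of ferroptosis, iron handling, Nrf2 targets, the integrated stress response, the unfolded protein response, p53 targets, G1/S, G2/M, replication-dependent histones, DNA damage checkpoint and repair, interferon-stimulated genes, NF-kB inflammatory genes, cholesterol synthesis, fatty acids and phospholipids, glycolysis and hypoxia, nuclear oxidative phosphorylation genes, mitochondrially encoded genes, ribosomal proteins, the Bcl2 family and caspases, epithelial and mesenchymal genes, immediate-early genes, heat shock genes, and markers of immune cells, stroma and blood. Lists with at least 5 tested members (24) were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists of a comparison, beside camera with an estimated correlation and fry. Counts for fry are of its directional test, and its mixed test is given for the direct comparison. Some genes are in more than 1 list and make an entry in each. Counts of rises and falls use the adjustment over all genes, and counts "adjusted over the list alone" repeat it within each list.

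Groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names Wee1; the 6 largest rises and 6 largest falls among called genes whose groups do not overlap and that have an official symbol; for each list 2 to 4 members with the smallest adjusted p, lists that pass coming before others; and the fixed genes Gpx4, Slc7a11, Acsl4, Tfrc, Hmox1, Ptgs2, Chac1, Fth1, Cdkn1a, Ccnb1, Cdk1, Ccne1, Pkmyt1, Atf4 and Ddit3. Of the lists that passed, mostly the leading 2 members are named, and of those that did not pass, mostly the counts alone. Nqo1, Cldn3 and the marker genes Cd14, Cd68, Pdgfra and Itga2b fall outside this rule or its order and were chosen after their values were seen.

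Alternatives fixed beforehand were pseudocounts of 0.1 and 0.01, no expression filter, a minimum mean of 5 FPKM, rescaling to a common total, median-of-ratios size factors, quantile normalization, the replicate number as a block, fits of only the 2 groups compared, eBayes without trend, array weights, the most abundant transcript per gene, an added log2 limit of 1, and leaving out each library in turn. Chosen after seeing the data were adding unnamed transcripts to the named gene where their locus holds exactly 1 (9599 transcripts), summing all transcripts of a locus, and leaving out genes without a transcript of 200 bases. Similarity of both comparisons with NC was set against 100 simulations of unchanged groups with the same controls.

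The procedure was tested on simulated data for MK1775 against NC over 10453 genes, with 200 genes changed in each of 10 runs. It recovered 82.9% of genes changed by 1 on the log2 scale and 46.2% of those changed by 0.5, with 4.4% of calls false. In the contrast left unchanged limma called 0 genes. A list shifted by 0.3 was called in 100% of runs. Noise in these runs was drawn independently for each gene, with no correlation between genes. In the data 41% of genes were called with MK1775, so the shares of false calls and of lists found may not carry over.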

Results

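Gene expression was profiled by RNA-seq in 4T1 cells, a mouse mammary carcinoma line of epithelial type, sampled at day 2. The 9 libraries fell into 3 groups of 3: a negative control (NC), cells given MK1775 (adavosertib, a small-molecule inhibitor of the Wee1 kinase), and cells labelled as given small interfering RNA (siRNA) against Wee1. Wee1 encodes a kinase that keeps Cdk1 inactive by phosphorylation and so restrains entry into mitosis. The title of the study links Wee1 targeting to sensitivity to ferroptosis, an iron-dependent form of cell death marked by lipid peroxidation, and its design sets each treated group against NC. Expression was given in FPKM, and the FPKM summed over all transcripts was 321551 to 332950 per library, with 10017 to 10783 named genes at 1 FPKM or more. FPKM values carry no read totals, so the depth of each library is unknown and no counting interval is given. The labels do not say that the replicates of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

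The 6 treated libraries lay together and apart from NC. On the leading principal component, which held 53.1% of the variance, the NC libraries scored between -37.8 and -33.6 and the treated libraries between 15.1 and 23.4. Pearson correlations across genes, which are not independent replicates, were 0.968 to 0.976 between MK1775 libraries and libraries labelled Wee1 siRNA, 0.937 to 0.942 between MK1775 and NC, and 0.921 to 0.939 between the siRNA-labelled libraries and NC. Replicate 3 of the siRNA-labelled group stood highest on the next component, at 23, followed by NC replicate 1 at 13.5. More annotated transcripts had a value above 0 in the treated groups, 61460 ± 921 with MK1775 and 60350 ± 1120 in the siRNA-labelled libraries against 55360 ± 577 in NC (SD, n = 3; exact two-sided permutation p = 0.1 for each, the smallest that 3 against 3 allows). Transcripts encoded by mitochondrial DNA took 1.63% ± 0.351 of FPKM in NC, 1.97% ± 0.0577 with MK1775 and 2.3% ± 0.458 in the siRNA-labelled libraries (SD, n = 3; exact permutation p = 0.4 and 0.2).

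**Figure D1:**
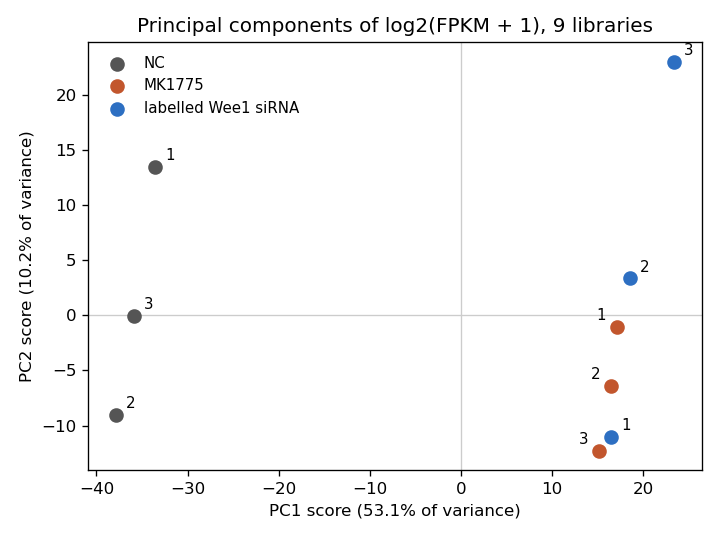
Scores of the 9 libraries on the leading 2 principal components of log2(FPKM + 1), which hold 53.1% and 10.2% of the variance; each point is a library and its number is the replicate. The 3 NC libraries lie on the left, at -37.8 to -33.6, and the 6 treated libraries on the right, at 15.1 to 23.4, with both treated groups overlapping along this axis.

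Wee1 itself, the gene targeted in both treatments, was not lower in any treated library than in NC. The gene lies on chromosome 7 from 109721253 to 109742700 on the plus strand (GRCm39). Its FPKM was 11.5, 10.5 and 11 in the NC libraries, 15, 14.7 and 16.8 with MK1775, and 13.1, 15.1 and 15.3 in the libraries labelled Wee1 siRNA. Against NC, Wee1 rose by 0.46 with MK1775 (log2, SE 0.078, 95% interval 0.28 to 0.64, limma adjusted p = 0.00226) and by 0.37 in the siRNA-labelled libraries (SE 0.078, 95% interval 0.19 to 0.55, adjusted p = 0.00633). The exact permutation p was 0.1 for both comparisons. As the transcript named by the siRNA label was not lowered, the third group is called "the libraries labelled Wee1 siRNA" throughout, and every direction drawn from it rests on that label alone.

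**Figure D2:**
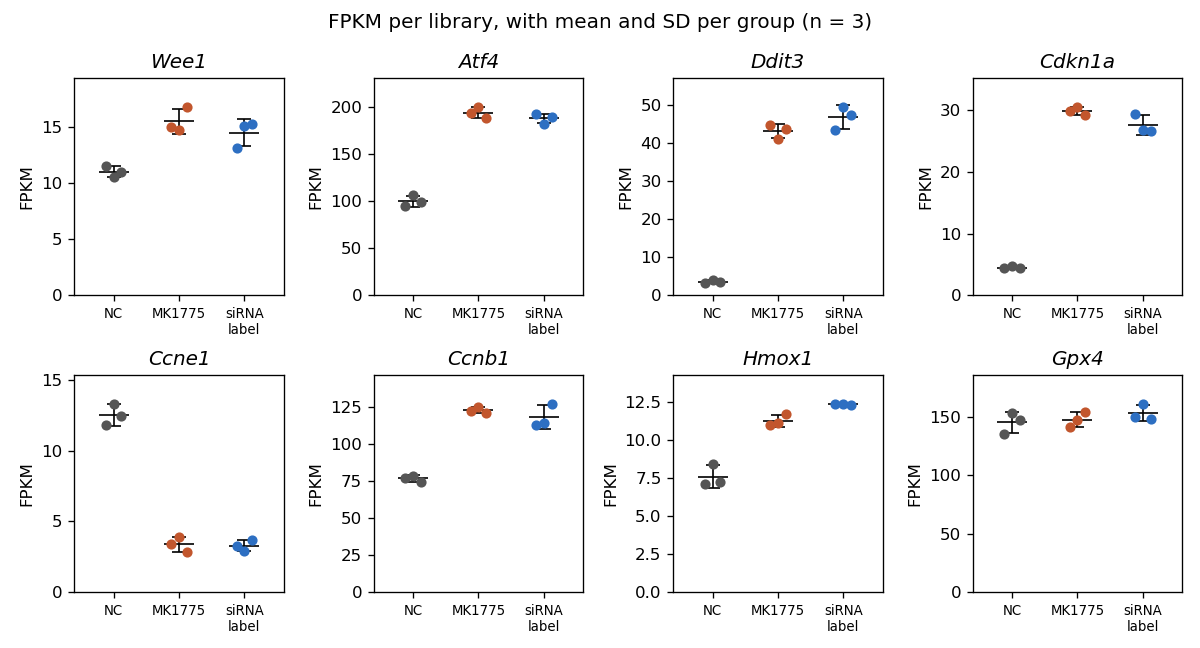
FPKM of 8 genes fixed for reporting before the data were examined, 1 panel per gene, with the 3 libraries of each group as points and the group mean and SD as black bars (n = 3). Wee1, Atf4, Ddit3, Cdkn1a, Ccnb1 and Hmox1 are higher in every treated library than in every NC library, Ccne1 is lower (12.5 in NC against 3.38 and 3.29), and Gpx4 overlaps between groups (145, 147 and 153).

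MK1775 was compared with NC to find which transcripts differ between these groups. The titles name NC only as negative control, and the same 3 NC libraries serve both comparisons. Any effect of vehicle, transfection or preparation that separates NC from the treated libraries cannot be told apart from that of the treatment. Replication-dependent histone genes are normally transcribed during DNA synthesis. Of 39 listed, 20 were tested and 19 rose (camera adjusted p = 0.051 with an estimated correlation). Of 25 genes of the integrated stress response 17 rose and 1 fell (camera adjusted p = 0.099 with an estimated correlation). The cytokine Il11 and the cyclin-dependent kinase inhibitor Cdkn1a (p21) also rose. Il11 went from 0.451 ± 0.114 FPKM in NC to 33.5 ± 0.642 (SD, n = 3), and Cdkn1a went from 4.49 ± 0.217 to 29.8 ± 0.635, a 6.65-fold difference. Of 43 genes of the G1/S transition 22 fell and 2 rose (adjusted p = 0.099 with an estimated correlation). Among the falls was cyclin E1 (Ccne1), which drives entry into S phase and went from 12.5 ± 0.782 to 3.38 ± 0.548. The matrix metalloproteinase Mmp3 fell from 107 ± 6.84 to 27.9 ± 1.21. Of 10453 genes tested with limma, 4282 (41%) differed at an adjusted p under 0.05, 1871 higher and 2411 lower, and 321 of the higher and 115 of the lower ones by at least 1 on the log2 scale. Which direction held more genes depended on scaling and filter, with 2120 higher and 2015 lower under median-of-ratios scaling and 2907 and 2168 without a filter. Without adjustment 5122 genes passed, where 523 are expected by chance. The 3 MK1775 values lay wholly outside the 3 NC values in 54% of genes, where chance gives 10%.

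The largest rises with MK1775 among genes with no overlap between groups were in Eif4a3l1 (4.91, SE 0.072), Il11 (4.57, SE 0.076, adjusted p = 1.34e-08), the histone genes H2bc4 (4.48, SE 0.14), H1f2 (4.19, SE 0.097) and H4c9 (3.87, SE 0.13), and Tcstv1 (3.98, SE 0.094), all on the log2(FPKM + 1) scale. Eif4a3l1 and Tcstv1, which belong to multi-copy families, were close to 0 in NC, at 0.0121 and 0.00799 FPKM, and reached 29.6 ± 2.94 and 15 ± 1.5. Among the largest falls was Mmp3 (-1.90, SE 0.063, adjusted p = 4.88e-07). Assembled transcripts without a gene name held 0% of FPKM at its locus in MK1775 and NC, so counting them could not change its value. The falls of Fhl2 and Leo1 rested on which transcripts carry the gene's name. Fhl2, a LIM-domain cofactor, fell by 3.12 in its named transcripts and was higher by 0.86 with the unnamed ones added. Leo1, a subunit of the Paf1 elongation complex, fell by 1.91 (SE 0.64, adjusted p = 0.0447) and was at 0.06 with them. Of 24 alternatives 10 kept the call of Leo1, 2 reversed its direction and 12 ended the call. Among those 12 were leaving out any NC library (-1.96 to -1.86), MK1775 replicate 1 (-2.04) or 2 (-1.28), or siRNA-labelled replicate 3 (-1.91). Sarnp and Kdm4dl fell by 3.09 and 2.77, and whole loci, which pool 2 and 4 named genes, fell by 1.14 and 0.84. Fam111a fell by 1.87, and by 1.20 with unnamed transcripts.

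Replication-dependent histone genes rose with MK1775 in 19 of 20 tested, and in 20 of 20 adjusted over the list alone, with a median log2 fold change of 2.32 (camera adjusted p = 4.43e-17, adjusted p = 0.051 with an estimated correlation). Of 39 listed genes 20 passed the filter, which genes high only in the treated libraries can pass, so the count of rises is favoured by it. The median was 1.17 without a filter and 5.33 with a pseudocount of 0.01. H3c2 went from 0.170 ± 0.0437 to 11.4 ± 0.594 FPKM and H1f2 from 5.62 ± 0.805 to 119 ± 9.78. These genes are near-identical copies, so the value of any single copy is uncertain. Summed over all 39 listed genes they came to 18.8 ± 2.80 FPKM in NC and 327 ± 20.4 with MK1775. In the same libraries the share of FPKM on transcripts without a gene name was 12.4% ± 0.265 against 10.5% ± 0.624 in NC.

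The integrated stress response list, genes induced when translation initiation is restrained, had 17 members that rose and 1 that fell of 25 tested (17 and 1 adjusted over the list alone), with a median of 0.76 (camera adjusted p = 1.92e-09, adjusted p = 0.099 with an estimated correlation). The transcription factors Ddit3 (CHOP) and Atf3 rose by 3.26 (SE 0.079) and 3.68 (SE 0.085), Atf4 rose from 99.7 ± 5.73 to 194 ± 5.88 FPKM, and Chac1, a glutathione-degrading enzyme, rose 2.56-fold from 8.90 ± 0.837. Immediate-early genes, which include Atf3 as well, had 14 rises and 5 falls of 25 (14 and 5 adjusted over the list alone, median 0.48, camera adjusted p = 0.000432, adjusted p = 0.25 with an estimated correlation), and Egr1 rose 7.14-fold from 2.61 ± 0.0821. Targets of p53 had 12 rises and 6 falls of 26 (12 and 6 adjusted over the list alone, median 0.21, camera adjusted p = 0.0298, adjusted p = 0.099 with an estimated correlation). Besides Cdkn1a (2.49, SE 0.057, adjusted p = 1.13e-07), Plk2 rose from 12.4 ± 0.485 to 44.0 ± 0.585 FPKM. The p53 call ended with a minimum mean of 5 FPKM, where the median was -0.05, and when unnamed transcripts were counted. Whether p53 drove any of these rises, in either treated group, was not tested.

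Cell-cycle lists moved in opposite directions with MK1775. G1/S genes had 22 falls and 2 rises of 43 (24 and 4 adjusted over the list alone, median -0.33, camera adjusted p = 0.000287, adjusted p = 0.099 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit, fell from 137 ± 1.71 to 52.0 ± 1.02 FPKM, and Uhrf1, a maintenance DNA methylation factor, fell from 74.3 ± 3.21 to 40.7 ± 0.524. With the most abundant transcript per gene in place of the sum, Uhrf1 was at -0.56 and no longer called. G2/M genes had 20 rises and 7 falls of 45 (21 and 7 adjusted over the list alone, median 0.38, camera adjusted p = 0.00168, adjusted p = 0.32 with an estimated correlation). Ube2c, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, rose 1.79-fold from 206 ± 3.69 FPKM and cyclin B1 (Ccnb1) rose 1.60-fold from 76.7 ± 2.22, while Pimreg fell by 1.11 (SE 0.071). Cdk1, the kinase that Wee1 inhibits, rose by 0.18 (SE 0.036, adjusted p = 0.00422). Pkmyt1, a related kinase that also phosphorylates Cdk1, was at 10.9 ± 0.469 and 11.7 ± 0.434 FPKM (0.10, adjusted p = 0.227).

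Epithelial genes had 8 rises and 2 falls of 14 with MK1775 (8 and 2 adjusted over the list alone, median 0.41, camera adjusted p = 0.00339, adjusted p = 0.25 with an estimated correlation), and keratin 18 (Krt18) rose from 251 ± 22.7 to 475 ± 4.91 FPKM. Grhl2, a transcription factor of epithelial identity, rose from 0.0202 ± 0.0143 to 1.94 ± 0.142. It passed the filter only through the treated libraries. Cldn3, also on this list, fell from 18.2 ± 1.21 to 10.1 ± 0.325 with unnamed transcripts added. Interferon-stimulated genes had 10 rises and 1 fall of 21 (10 and 1 adjusted over the list alone, median 0.29, camera adjusted p = 0.00103, adjusted p = 0.099 with an estimated correlation). The chemokine gene Cxcl10 rose from 0.318 ± 0.0178 to 2.50 ± 0.230 FPKM and the peptide transporter gene Tap1 from 3.47 ± 0.0328 to 8.69 ± 0.394. With a minimum mean of 5 FPKM, which drops low genes such as Cxcl10 and Grhl2, neither list was called.

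With MK1775 the cholesterol synthesis list had 15 falls and 1 rise of 25 (15 and 1 adjusted over the list alone, median -0.31, camera adjusted p = 0.00517, adjusted p = 0.099 with an estimated correlation), led by Insig1, a sterol sensor, at 2.36-fold lower. The fatty acid and phospholipid list had 16 falls and 3 rises of 30 (16 and 4 adjusted over the list alone, median -0.39, camera adjusted p = 0.0169, adjusted p = 0.099 with an estimated correlation), and the desaturases Fads2 and Fads1, which make polyunsaturated fatty acids, went from 31.6 ± 2.05 to 11.5 ± 0.561 and from 17.9 ± 0.593 to 9.54 ± 0.232 FPKM. Heat shock genes had 9 falls and 1 rise of 19 (9 and 1 adjusted over the list alone, median -0.26, camera adjusted p = 0.0206, adjusted p = 0.099 with an estimated correlation), with the chaperones Hspe1 and Fkbp4 at 1.52-fold and 1.76-fold lower. Glycolysis and hypoxia genes had 13 falls and 3 rises of 27 (14 and 3 adjusted over the list alone, median -0.21, camera adjusted p = 0.0323, adjusted p = 0.33 with an estimated correlation). Hexokinase 2 (Hk2) fell by 0.78 and Ndrg1, a hypoxia-induced gene, rose by 0.87. A minimum mean of 5 FPKM ended the heat shock and glycolysis calls, and quantile normalization or the most abundant transcript per gene also ended that of glycolysis.

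Genes tied to ferroptosis did not pass camera as a group with MK1775, while fry called suppressors of ferroptosis (adjusted p = 0.019) and iron handling genes (adjusted p = 0.0017) downward. Suppressors of ferroptosis had 2 rises and 8 falls of 21 (2 and 8 adjusted over the list alone, camera adjusted p = 0.399). Slc3a2, the heavy chain of the cystine transporter, rose from 64.0 ± 3.93 to 109 ± 3.89 FPKM and Gch1, which starts tetrahydrobiopterin synthesis, from 1.27 ± 0.139 to 3.82 ± 0.0754, while Nfs1, a cysteine desulfurase, fell 1.92-fold from 17.4 ± 1.09 (-0.87, and -0.30 over its whole locus, which holds 4 named genes) and Prdx6, a peroxiredoxin, fell from 189 ± 15.6 to 127 ± 4.52. The lipid peroxidase Gpx4 was at 145 ± 9.37 and 147 ± 6.66 (0.02, SE 0.060, adjusted p = 0.784). Promoters and markers of ferroptosis had 3 rises and 7 falls of 25 (3 and 7 adjusted over the list alone, camera adjusted p = 0.796). Besides Chac1, heme oxygenase 1 (Hmox1) rose from 7.60 ± 0.740 to 11.3 ± 0.407 FPKM, while Acsl4, which loads polyunsaturated fatty acids into lipids, went from 13.3 ± 3.75 to 9.09 ± 0.583 (-0.47, adjusted p = 0.0982; -0.67 and called without NC replicate 2) and Ptgs2 from 24.8 ± 2.68 to 28.0 ± 3.42 (adjusted p = 0.417). Iron handling genes had 2 rises and 6 falls of 21 (2 and 5 adjusted over the list alone, camera adjusted p = 0.399), ferritin heavy chain (Fth1) was at 1390 ± 81.8 and 1300 ± 58.3 (adjusted p = 0.422), and the transferrin receptor (Tfrc) fell from 35.3 ± 8.69 to 18.3 ± 4.54 (-0.90, adjusted p = 0.0486). Of 24 alternatives 13 ended the call of Tfrc, among them leaving out NC replicate 1 (-0.85) or 2 (-0.75), MK1775 replicate 1 (-0.83) or 2 (-0.79), or siRNA-labelled replicate 1 (-0.90). With unnamed transcripts added Tfrc went from 52.1 ± 9.17 to 25.6 ± 0.981 (-0.98, called there). Slc7a11, the light chain of the cystine transporter, was at 0.215 ± 0.322 and 0.121 ± 0.0697 in its named transcripts, too low to be tested, but at 0.656 ± 0.0611 and 1.74 ± 0.175 with unnamed transcripts added (0.73, called there).

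Of the other lists tested with MK1775, Nrf2 targets had 4 rises and 8 falls of 29 (4 and 8 adjusted over the list alone, camera adjusted p = 0.873), unfolded protein response genes 5 and 6 of 23 (6 and 6; 0.796), DNA damage checkpoint and repair genes 8 and 12 of 44 (8 and 12; 0.796) and NF-kB inflammatory genes 10 and 6 of 25 (10 and 6; 0.187). Nuclear genes of oxidative phosphorylation had 4 rises and 6 falls of 32 (3 and 4 adjusted over the list alone, camera adjusted p = 0.962), mitochondrially encoded genes 1 and 1 of 10 (1 and 1; 0.399), ribosomal proteins 3 and 7 of 38 (3 and 6; 0.765), the Bcl2 family and caspases 5 and 9 of 23 (5 and 9; 0.441), and mesenchymal genes 3 and 5 of 19 (3 and 5; 0.796). For the unfolded protein response the median was 0.01, the mean 0.00 and the directions of camera and fry differed. Markers of immune cells, stroma and blood stayed low. No list of them had 5 genes at the minimum. Cd68, an immune marker, fell from 3.69 ± 0.239 to 2.23 ± 0.423 with MK1775. The highest mean of an immune marker was 5.65 FPKM (Cd14, in NC), and of a stromal marker 1.60 (Pdgfra, in the siRNA-labelled libraries), and of a blood marker 1.06 (Itga2b, in the same libraries). In all, 12 of 24 lists passed camera, 7 upward and 5 downward. With an estimated correlation no list passed (8 at an unadjusted p under 0.05), and 16 passed fry, which asks only whether a list's own genes move one way.

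**Figure D3:**
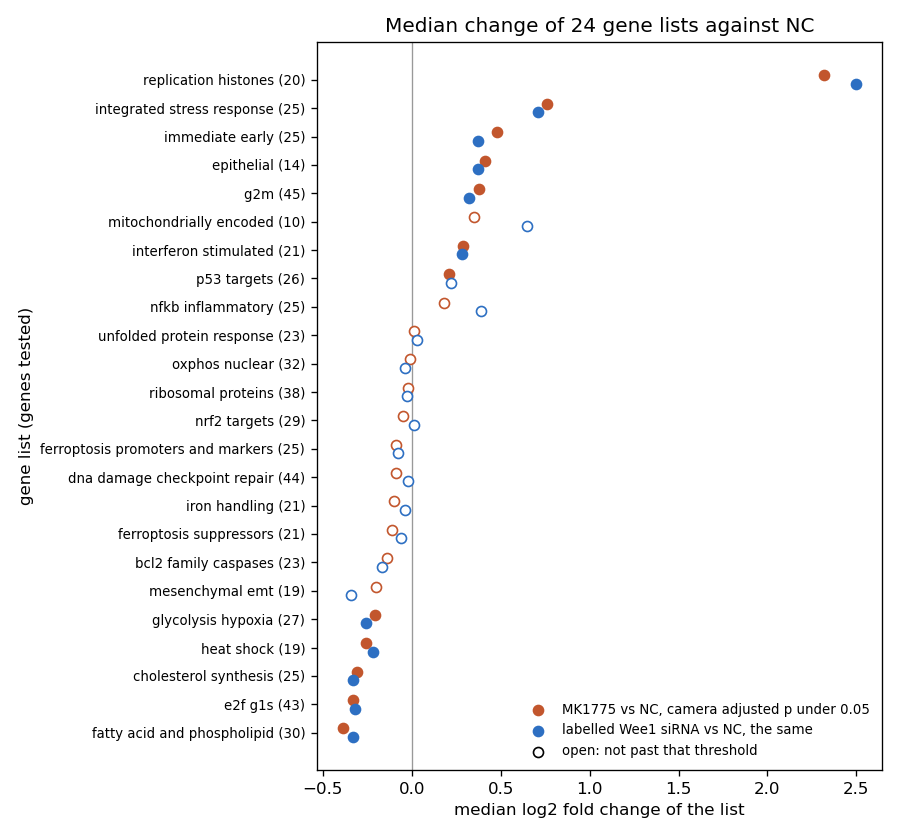
Median log2 fold change against NC of the 24 gene lists tested, with the number of genes tested in parentheses; filled points are lists with a camera adjusted p under 0.05 and open points are lists above it. Replication histones stand apart at 2.32 (MK1775) and 2.50 (labelled Wee1 siRNA), and the ferroptosis lists lie near 0, at -0.11 and -0.09 with MK1775.

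The libraries labelled Wee1 siRNA were compared with NC to set depletion of the kinase beside its inhibition. As Wee1 was higher in them than in NC, the directions below describe the label only. Of 39 listed histone genes 20 were tested and 19 rose (camera adjusted p = 0.062 with an estimated correlation). Of the stress response genes 19 rose and 1 fell of 25 (adjusted p = 0.094 in the same test). Of the immediate-early genes 14 rose and 4 fell of 25 (adjusted p = 0.23 in the same test). Il11 was at 33.0 ± 2.21 FPKM, Cdkn1a at 27.6 ± 1.60 and Ddit3 at 46.7 ± 3.09 (SD, n = 3), against 0.451 ± 0.114, 4.49 ± 0.217 and 3.61 ± 0.409 in NC. Ccne1 fell 3.80-fold to 3.29 ± 0.373 and Mmp3 fell 3.66-fold to 29.2 ± 1.51. Of 10453 genes, limma called 4474 (42.8%), 2048 higher and 2426 lower, of which 376 and 114 by at least 1 on the log2 scale. The balance turned with rescaling to a common total (2247 higher, 2202 lower), median-of-ratios scaling (2214 and 2201), no filter (3558 and 2249) and whole loci (3255 and 3110). Without adjustment 5271 genes passed, where 523 are expected by chance, and the groups did not overlap in 52.2% of genes, where chance gives 10%.

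The largest rises in the siRNA-labelled libraries were in Eif4a3l1 (5.20, SE 0.072), Il11 (4.55, SE 0.076, adjusted p = 1.39e-08), Tcstv1 (4.51, SE 0.094), H2bc4 (4.36, SE 0.14), H1f2 (4.14, SE 0.097) and H4c9 (3.88, SE 0.13). Of the falls, that of Mmp3 was -1.84 (SE 0.063, adjusted p = 5.52e-07). Bola1 fell by 2.41, Fdx2 by 2.04 and Nap1l4 by 1.93 in their named transcripts, and whole loci, which pool 2, 6 and 2 named genes, gave -0.82, -0.81 and -0.48. Fhl2 fell by 2.22 and Mpc2, a subunit of the mitochondrial pyruvate carrier, by 1.71, and both were higher, at 0.81 and 0.16, once unnamed transcripts were added.

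Lists that rose in the siRNA-labelled libraries began with the replication-dependent histones, 19 of 20 (19 adjusted over the list alone, median 2.50, camera adjusted p = 8.32e-16, adjusted p = 0.062 with an estimated correlation). H3c2 was at 11 ± 0.824 FPKM against 0.170 ± 0.0437. Here too only 20 of 39 listed histone genes passed the filter, which genes high only in the treated libraries can pass. The histone median was 0.97 without a filter and 5.30 with a pseudocount of 0.01. Unnamed transcripts held 12.6% ± 0.265 of FPKM in these libraries. The integrated stress response had 19 rises and 1 fall of 25 (19 and 1 adjusted over the list alone, median 0.71, camera adjusted p = 2.5e-08, adjusted p = 0.094 with an estimated correlation). Ddit3 rose by 3.37 and Atf3 by 3.55, Atf4 rose 1.88-fold and Chac1 2.11-fold. Immediate-early genes had 14 rises and 4 falls of 25 (14 and 4 adjusted over the list alone, median 0.37, camera adjusted p = 0.000528, adjusted p = 0.23 with an estimated correlation). Egr1 was at 18.7 ± 1.51. G2/M genes had 18 rises and 5 falls of 45 (19 and 7 adjusted over the list alone, median 0.32, camera adjusted p = 0.00449, adjusted p = 0.35 with an estimated correlation). Ube2c rose to 349 ± 4.95 and Ccnb1 to 118 ± 7.5, and Pimreg fell to 15.2 ± 1.46. Epithelial genes had 8 rises and 2 falls of 14 (8 and 2 adjusted over the list alone, median 0.37, camera adjusted p = 0.00449, adjusted p = 0.23 with an estimated correlation). Krt18 was at 435 ± 1.24 and Grhl2 at 1.94 ± 0.0759. Cldn3 fell from 18.2 ± 1.21 to 9.94 ± 0.997 with unnamed transcripts added. Interferon-stimulated genes had 10 rises and 2 falls of 21 (10 and 2 adjusted over the list alone, median 0.28, camera adjusted p = 0.00449, adjusted p = 0.14 with an estimated correlation). Cxcl10 rose to 1.90 ± 0.106 and Tap1 to 8.08 ± 0.692, while Lgals3bp fell from 21.5 ± 1.78 to 9.35 ± 0.278. A minimum mean of 5 FPKM ended the epithelial and interferon calls here too. Targets of p53 had 12 rises and 7 falls of 26 (12 and 7 adjusted over the list alone, median 0.22) and did not pass camera (adjusted p = 0.0505). The direct test of the p53 list between both treated groups gave a median of 0.01 (camera adjusted p = 0.789). Cdkn1a rose by 2.38 (SE 0.057) and Plk2 by 1.58 (SE 0.048).

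Lists that fell in the siRNA-labelled libraries were the same 5 as with MK1775. G1/S genes had 24 falls and 3 rises of 43 (25 and 4 adjusted over the list alone, median -0.32, camera adjusted p = 4.29e-05, adjusted p = 0.094 with an estimated correlation). Rrm2 was at 49.9 ± 1.09 and Uhrf1 at 40.4 ± 1.54 FPKM. Cholesterol synthesis had 12 falls and 1 rise of 25 (13 and 1 adjusted over the list alone, median -0.33, camera adjusted p = 0.00868, adjusted p = 0.094 with an estimated correlation). Insig1 was 2.41-fold lower. Fatty acid and phospholipid genes had 16 falls and 5 rises of 30 (16 and 5 adjusted over the list alone, median -0.33, camera adjusted p = 0.012, adjusted p = 0.094 with an estimated correlation). Fads2 was at 10.7 ± 0.929 and Fads1 at 9.21 ± 0.653. Glycolysis and hypoxia genes had 13 falls and 3 rises of 27 (14 and 3 adjusted over the list alone, median -0.26, camera adjusted p = 0.0102, adjusted p = 0.23 with an estimated correlation). Hk2 was at 7.35 ± 0.353 and Ndrg1 higher at 61.5 ± 3.04. Heat shock genes had 8 falls and 2 rises of 19 (8 and 2 adjusted over the list alone, median -0.22, camera adjusted p = 0.0408, adjusted p = 0.14 with an estimated correlation). Hspe1 was at 136 ± 2.94 and Fkbp4 at 63.8 ± 1.30. A minimum mean of 5 FPKM ended the glycolysis and heat shock calls, and 5 other alternatives ended the latter, among them leaving out replicate 3 of this group (median -0.14).

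Ferroptosis genes in the libraries labelled Wee1 siRNA again went both ways, and of the 3 lists fry called iron handling downward (adjusted p = 0.0039). Suppressors had 4 rises and 7 falls of 21 (4 and 7 adjusted over the list alone, camera adjusted p = 0.587). Slc3a2 rose to 105 ± 0.934 and Gch1 to 3.99 ± 0.192 FPKM. Nfs1 fell to 9.86 ± 0.209 and Prdx6 to 122 ± 3.90, and Gpx4 was at 153 ± 6.78 (0.08, SE 0.060, adjusted p = 0.341). Promoters and markers had 5 rises and 8 falls of 25 (5 and 8 adjusted over the list alone, camera adjusted p = 0.681). Hmox1 rose to 12.4 ± 0.0411, and Acsl4 (10.5 ± 2.20, adjusted p = 0.265) and Ptgs2 (30.1 ± 5.41, adjusted p = 0.201) did not pass, though Ptgs2 did without replicate 1 of this group (0.41). Iron handling had 3 rises and 6 falls of 21 (3 and 6 adjusted over the list alone, camera adjusted p = 0.451). Fth1 was at 1460 ± 179 (adjusted p = 0.617) and Tfrc at 22.5 ± 10.1 (-0.68, adjusted p = 0.115; -1.01 and called without replicate 3 of this group). With unnamed transcripts added, Tfrc went from 52.1 ± 9.17 to 29.2 ± 5.52 (-0.81, called there) and Slc7a11 from 0.656 ± 0.0611 to 2.19 ± 0.461 (0.94, called there). Cdk1 was at 44.1 ± 0.811 (0.08, adjusted p = 0.0935) and Pkmyt1 at 11.4 ± 0.628 (0.06, adjusted p = 0.455).

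For the remaining lists in the siRNA-labelled libraries, Nrf2 targets had 6 rises and 6 falls of 29 (6 and 6 adjusted over the list alone, camera adjusted p = 0.999), unfolded protein response genes 5 and 6 of 23 (6 and 6; 0.961), DNA damage checkpoint and repair genes 9 and 11 of 44 (9 and 11; 0.999), and NF-kB inflammatory genes 12 and 5 of 25 (12 and 6; 0.171). Oxidative phosphorylation had 5 rises and 8 falls of 32 (5 and 8 adjusted over the list alone, camera adjusted p = 0.827), ribosomal proteins 3 and 5 of 38 (3 and 4; 0.587), the Bcl2 family and caspases 6 and 9 of 23 (6 and 9; 0.578), mesenchymal genes 3 and 6 of 19 (3 and 7; 0.539), and 3 of 10 mitochondrially encoded genes rose (3; 0.261). Median and mean differed in sign for Nrf2 targets (0.01 and -0.01), the unfolded protein response (0.03 and -0.01) and oxidative phosphorylation (-0.04 and 0.04), and the median for DNA damage was -0.02 with a mean of 0.00. In all, 11 of 24 lists passed camera, 6 upward and 5 downward. With an estimated correlation no list passed (8 at an unadjusted p under 0.05), and 15 passed fry.

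Both sets of fold changes were nearly the same across genes. Pearson's r over the 10453 genes was 0.914, where 100 simulations of unchanged groups against the same 3 controls gave 0.5 (SD 0.023), and genes are not independent replicates. The covariance was 0.263 against 0.0187 in the simulations, a difference of 0.244. Called in both comparisons were 1670 genes higher in both and 2103 lower in both, where independent lists of these sizes would share 367 and 560, and no gene was called in opposite directions. Il11, Ddit3, Cdkn1a, Ccne1 and Mmp3 were among the genes shared. With only 3 control libraries these could not be divided, so part of the excess may come from the shared controls.

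**Figure D4:**
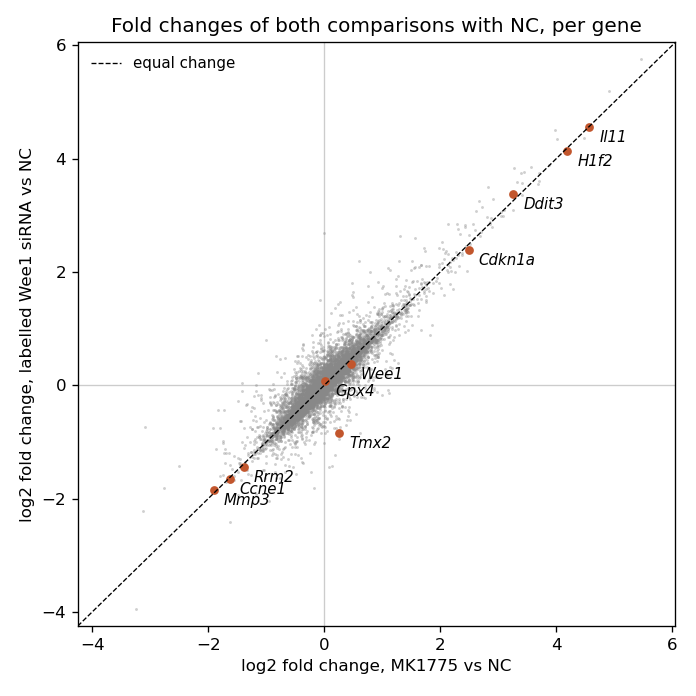
Log2 fold change of each of the 10453 genes tested in the libraries labelled Wee1 siRNA against NC (vertical) and with MK1775 against NC (horizontal), on the log2(FPKM + 1) scale; the dashed line marks equal change and the named genes are drawn in colour. Points follow the line (r = 0.914), Il11, H1f2, Ddit3 and Cdkn1a lie high on it, Mmp3, Ccne1 and Rrm2 low, and Tmx2 lies off it.

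The direct comparison of MK1775 with the libraries labelled Wee1 siRNA, the test of the difference itself, called 1 gene. Tmx2, which encodes a thioredoxin-related membrane protein on chromosome 2 (84501660 to 84509484, minus strand), was at 23.6 ± 3.03 FPKM with MK1775 and 10.4 ± 0.333 in the siRNA-labelled libraries (SD, n = 3), against 19.5 ± 1.12 in NC, a difference of 1.10 (SE 0.092, limma adjusted p = 0.0232). The difference was 0.16 when all transcripts of its locus, which holds 5 named genes, were summed. Of 24 alternatives 11 ended the call, among them leaving out any library other than MK1775 replicate 1 (1.03 to 1.12). At an unadjusted p under 0.05 there were 616 genes, where 523 are expected by chance, and groups did not overlap in 11.9% of genes, where chance gives 10%. For 9490 genes (90.8%) the 95% interval of the difference lay within 1 log2 unit of 0, and the median half-width was 0.24. Of the fixed genes, Chac1 differed by 0.27 (95% interval 0.11 to 0.42), Cdk1 by 0.10 (0.02 to 0.18), Wee1 by 0.09 (-0.09 to 0.27), Cdkn1a by 0.11 (-0.02 to 0.24), Ddit3 by -0.11 (-0.29 to 0.07), Ccne1 by 0.03 (-0.23 to 0.28), Gpx4 by -0.05 (-0.19 to 0.09) and Tfrc by -0.22 (-0.94 to 0.49), and no adjusted p of theirs passed. Camera called none of the 24 lists (1 at an unadjusted p under 0.05, the mesenchymal genes at a median of 0.06; lowest adjusted p = 0.566), and neither camera with an estimated correlation nor fry's directional test called any (0 each at an unadjusted p under 0.05). Fry's mixed test, which asks whether a list's genes differ in either direction, called interferon-stimulated genes (adjusted p = 0.0016) and NF-kB inflammatory genes (adjusted p = 0.0084). Adjusted over the list alone, 1 ferroptosis suppressor, the quinone reductase gene Nqo1, was lower with MK1775 (-0.35, SE 0.076).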

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

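The tests of the 10 splits of each comparison, fry's mixed test over them and the use of the Wee1 level were chosen after the results were seen, and the test of whether both treated groups differ was written before its result.

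Tmx2 stood out because its effect differed between both treated groups in a test of the difference itself. It was higher by 1.10 with MK1775 than in the libraries labelled Wee1 siRNA (95% interval 0.89 to 1.31, limma adjusted p = 0.0232). Tmx2 was picked as the only gene called of 10453, so the lack of overlap between its groups adds no support. Of 24 alternatives 11 ended the call. Summed over the Tmx2 locus, which holds 5 named genes, the difference was 0.16.

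Transcripts without a gene name, which the comparisons of the report leave out, stood out because they held a larger share of FPKM than in the controls. They took 12.4% ± 0.265 of FPKM with MK1775 and 12.6% ± 0.265 in the siRNA-labelled libraries, against 10.5% ± 0.624 in NC (SD, n = 3; exact permutation p = 0.1 for each, the smallest possible). Tested one by one with limma, 924 of 6835 were higher and 94 lower with MK1775 (1730 at an unadjusted p under 0.05), and 998 were higher and 98 lower in the siRNA-labelled libraries (1838 unadjusted). Between both treated groups 1 was higher and 2 were lower (471 unadjusted). Of 17991 such transcripts 6835 were tested. If they were assembled or filtered over all 9 libraries, those high only in treated libraries could enter. The excess of rises against NC may be favoured by this and is no support for a general gain. Transcripts without a gene name took over part of the signal of Fhl2, Leo1 and Mpc2, whose falls in named transcripts ended when they were added.

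The libraries labelled Wee1 siRNA resembled the MK1775 libraries and did not show lower Wee1, which was 0.37 above NC (95% interval 0.19 to 0.55), the observation itself and no separate test of its cause. What stays open is that the 6 treated libraries may not differ by group, as with the same treatment under 2 labels. The real split gave 598 genes at an unadjusted p under 0.05, and 1 of the other 9 splits of these libraries gave at least as many. This lies within the 293 to 795 of those 9, the result set beforehand for no difference by group. Fry's mixed test called 2 lists in the real split (interferon-stimulated, adjusted p = 0.0016, and NF-kB inflammatory, 0.0084) and at most 1 in the other 9. That test was chosen after these 2 lists were known, and with 10 splits neither result can decide. A recovery of the transcript by day 2 after an earlier loss, and an siRNA acting on the protein without lowering the transcript, were not tested.

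For MK1775 against NC, the real split of the 6 libraries called 4215 genes and the highest of the others called 1, and for the siRNA-labelled libraries these were 4021 and 1; in each, 1 split gave a result as large, the real one. For the direct comparison the real split called 1 gene and the highest other 4, and 4 splits gave at least as many. With 10 splits each, no share can be under 0.1.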

How the results depend on the processing

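The tests with unnamed transcripts added, whole loci summed or short genes left out were chosen after the results were seen. Wee1 kept its direction and call against NC in 48 of 48 comparisons with an alternative, from 0.40 to 0.53 (MK1775) and from 0.33 to 0.46 (siRNA-labelled). Over single genes and list medians, 6356 of 6497 comparisons kept direction and call, 84 lost a call, 31 gained one and 26 reversed. Median histone changes went from 1.17 (MK1775) and 0.97 (siRNA-labelled) without a filter to 5.33 and 5.30 with a pseudocount of 0.01. Without known depth, no limit from counting can be given for low genes. Except where named, the cause was not tested.

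Genes called were 436 (MK1775) and 490 (siRNA-labelled) with a log2 limit of 1, which by construction keeps fewer, and 3068 to 6069 and 3191 to 6365 elsewhere. Lists called were 7 and 7 with a minimum mean of 5 FPKM, where fewer genes are tested, and 0 and 0 with an estimated correlation (8 and 8 unadjusted; 16 and 15 by fry). With the replicate block limma called 3881, 4079 and, directly, 0 genes (559 unadjusted). Libraries with the same number correlated at -0.12 to 0.043 after group means were removed, so the numbers give no sign of pairing. Directly, limma called 11 genes without filter, 2 with the most abundant transcript (Tmx2 and H2-K1), 0 over whole loci (733 unadjusted), 3 without MK1775 replicate 1 (Tmx2, Eif3c and Gadd45gip1), 1 without NC replicate 3 or with only the 2 groups (Frrs1), and 0 without any other library (521 to 899 unadjusted). Lists called directly were 1 (mesenchymal) without filter, with unnamed transcripts or over loci, 1 (G2/M) without siRNA-labelled replicate 3, and 0 without any other library by camera (1 unadjusted with all libraries). These genes and lists were named after their values were seen.

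The correlation of both sets of fold changes (0.914) moved to 0.928 and 0.947 with pseudocounts of 0.1 and 0.01, 0.928 at 5 FPKM, 0.899 with quantile normalization, 0.870 with the most abundant transcript, 0.961 with unnamed transcripts, 0.975 over loci, and 0.888 (without siRNA-labelled replicate 1) to 0.921 (without NC replicate 1) with a library left out.

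Reversed with unnamed transcripts and over loci were Fhl2 (0.86 with MK1775, 0.81 siRNA-labelled), Leo1 (0.06) and Mpc2 (0.16), as unnamed transcripts there rose. Reversed over loci were Pdgfra with MK1775 (-0.50) and Pdgfra in the siRNA-labelled libraries (-0.35). Quantile normalization turned Pdgfra with MK1775 (-0.10) and Fth1 in the siRNA-labelled libraries (-0.01), and the most abundant transcript turned Fth1 with MK1775 (0.07) and Pkmyt1 in the siRNA-labelled libraries (-0.15). With a library left out, Pdgfra with MK1775 went from -0.07 (without NC replicate 3; -0.01 without NC replicate 2, -0.05 without MK1775 replicate 1) to 0.32, Gpx4 from -0.03 (without NC replicate 1; -0.01 without MK1775 replicate 3) to 0.07, and Fth1 in the siRNA-labelled libraries from 0.00 (without its replicate 2) to 0.17. Directly, Tfrc went from -0.43 to 0.11 (without siRNA-labelled replicate 3), Ptgs2 from -0.25 to 0.01 (without MK1775 replicate 2), Ccne1 from -0.06 (without MK1775 replicate 2; -0.04 without siRNA-labelled replicate 2) to 0.12, and Pkmyt1 to 0.00 (without siRNA-labelled replicate 3). Apart from Fhl2, Leo1 and Mpc2, these genes were not called in the values of the report.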

Other observations

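The tests of S phase and the choice of genes and families in this part came after their values were seen, and the tests of RNA without a poly(A) tail, of copies and of low transcripts were written before their results.

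Among genes outside the naming rule, Txnip, a glucose-responsive regulator of thioredoxin, rose from 16.9 ± 0.669 FPKM in NC to 171 ± 2.23 with MK1775 and 151 ± 7.31 in the libraries labelled Wee1 siRNA (3.26 and 3.09, SE 0.047; limma adjusted p = 8.86e-09 and 9.16e-09). Atf5, a stress-response transcription factor, rose from 24.5 ± 1.90 to 183 ± 6.09 and 182 ± 13.5. Csn3, which encodes kappa-casein, a milk protein, rose from 12.9 ± 2.39 to 81.3 ± 6.08 and 82.0 ± 7.84. Plau, the urokinase gene, fell from 63.3 ± 4.61 to 21.8 ± 0.565 and 21.3 ± 0.0946. The cytoplasmic actins fell, Actb from 957 ± 185 to 279 ± 91.9 and 308 ± 18.7, and Actg1 from 564 ± 62.1 to 238 ± 10.7 and 221 ± 10.8. These 6 genes, chosen after their values were seen, kept direction and call in 24 of 24 alternatives.

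Multi-copy families of the cleavage-stage embryo, also chosen after their values were seen, were higher in both treated groups than in NC. Of 100 members of 10 families, 32 were tested, and 27 rose with MK1775 and 28 in the siRNA-labelled libraries. As several families were at or near 0 in NC, their members could pass the filter only through the treated libraries. These counts were therefore largely set by the filter and are no support for a rise. Zscan4 genes were listed at 0 FPKM in all NC libraries and summed to 4.73 ± 0.394 and 5.58 ± 1.11, and Zfp352, also at 0, reached 9.50 ± 1.09 and 12.5 ± 1.34. Usp17l genes went from 0.106 ± 0.0172 to 13.4 ± 1.41 and 17.6 ± 1.04, Tcstv genes from 0.00799 ± 0.0138 to 24.6 ± 2.30 and 33.1 ± 3.27, Spopfm genes from 0.0103 ± 0.00940 to 15.5 ± 2.84 and 17.5 ± 0.600, and Pramel genes from 4.45 ± 0.445 to 40.6 ± 2.85 and 48.9 ± 2.53. Eif1ad genes went from 13.9 ± 0.536 to 47.6 ± 4.96 and 63 ± 16.6, and the Duxf gene, listed at 0 in NC, reached 0.424 ± 0.0976 and 0.569 ± 0.0673.

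For these families, reads moved between near-identical copies within them are argued against by their sum, which was 9.97 times as high in the lowest treated library as in the highest NC library (18.6 ± 0.405, 201 ± 18.5 and 252 ± 35.7 FPKM). A general gain in detection of low transcripts stays open, as the families were chosen for their rise and 65.4% (MK1775) and 67.2% (siRNA-labelled) of 17334 other low genes were higher too, with 21.7% and 18.9% lower. The median gain of those other genes was 0.0145 FPKM at most, against 0.430 and 0.631 for 82 family members. Transcription of these families in some or all treated cells, a hypothesis from these data, and reads from sequences outside the families also stay open and were not tested, and which copy is expressed remains uncertain.

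Replication-dependent histone transcripts were higher in both treated groups. A larger share of cells in S phase stays open. The G1/S list had a median of -0.33 with MK1775 (22 fell and 2 rose of 43). In the siRNA-labelled libraries its median was -0.32 (24 and 3). Camera gave this list adjusted p = 0.099 and 0.094 with an estimated correlation. It covers the G1/S transition and was taken up after its fall was seen, so it cannot tell the share of cells in S phase. For more RNA without a poly(A) tail, 19 other such genes had medians of -0.26 (95% interval -0.51 to -0.10) and -0.15 (-0.43 to -0.01). Histones were at 2.32 and 2.50. Of the 19, 0 rose in either group, and 4 and 1 fell. The most abundant, Rn18s, was at -1.73 and -1.20 (limma adjusted p = 0.0055 and 0.026). Most of the others are small nucleolar RNA genes at low FPKM. As a set these genes did not rise with the histones. With most at low FPKM and Rn18s ranging from 543 to 1330 in NC, they cannot settle the explanation. It stays open for RNA without a poly(A) tail. Reads moved between near-identical copies are argued against by the sum, 14.3 times as high in the lowest treated library as in the highest NC library. Histone transcripts that gain a poly(A) tail, which cells may make when they leave the cycle or differentiate, stay open and were not tested.

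Genes under 0.1 FPKM in all NC libraries and at 1 or more in all treated libraries numbered 82 with MK1775 and 100 in the siRNA-labelled libraries. No gene met the converse in either, a count of values with no test. Treated libraries had more genes at 0.1 FPKM or more, which favours this direction. These were 15830 ± 118 with MK1775 and 16270 ± 263 in the siRNA-labelled libraries, against 13970 ± 156 in NC (SD, n = 3). Of 104 gene families formed from symbols, camera called none, the lowest adjusted p being 0.108 for Klf genes (6 rose and 2 fell of 11).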
